A study of Mus musculus with 19 samples.

How the data were processed

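The series profiled Melan-a cells, an immortalised line of mouse melanocytes, with and without a knockout of Bap1 made by CRISPR, and tumours grown from the Melan-a model under the skin or in the eye. Bulk RNA-seq covered 5 lines, the unedited parental line and 4 knockout clones, with 2 cultures of each that the labels call biological replicates, so 10 libraries in all. The labels put every library in one batch. The labels do not say whether the 2 cultures of a line were grown apart from the start. A p-value for a single clone, or for the clones against each other, therefore measures the spread between these cultures. With the clone as the unit, a p-value measures the spread among the lines, and the gene lists were tested on the same line values. Single-cell RNA-seq covered dissociated tumour tissue in 4 matrices held under one sample of the series. The genotype and the site of each matrix come only from the names the submitters gave the matrices, so each is called "the matrix labelled" with that name. The whole-genome libraries of B16F10 cells, Melan-a cells and primary ocular melanocytes and the whole-exome libraries of the 5 lines were not analysed here.

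Bulk values were deposited as a table of variance-stabilised expression on a log2-like scale, which per the file's values flattens at low counts, for 13202 genes. Its lowest value was 6.61, which marked 1005 values with no reads. Stranded libraries were made from polyadenylated RNA, per the labels' protocols, and the builds GRCm38 and mm10 stand in the submitters' processing notes. The bulk aligner, the counting tool and the package behind the stabilised values are not given in the sources used here. The stabilised values inverted to whole read counts, with 100% of the values within 0.01 of a whole number in every library. The recovered totals ran from 30.8 to 46.8 M reads per library. A change of 1 unit near the lowest value is a larger change in reads, so the differences printed below understate the change of weakly expressed genes.

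Single-cell matrices were deposited as raw UMI counts per gene and barcode, written by Cell Ranger 8.0.0 for 3 matrices and 7.0.0 for the matrix labelled WT ocular, per the file headers. That matrix listed 32285 genes and barcodes of 16 bases, against 19059 genes and 24 bases in the other 3, so it came from another assay or workflow. The labels name both a 3' chemistry and a fixed-tissue workflow. A list of 19059 genes resembles a set of probes, and the positions of the Bap1 probes or tags and of the edits are not given in the sources used here. A probe or 3' tag outside the edited part checks a knockout label only where the edit lowers the transcript itself. The 4 matrices held 11810 barcodes and 88.8 M UMIs (WT skin), 13167 and 91.2 M (KO skin), 38176 and 108.6 M (WT ocular), and 11283 and 115.6 M (KO ocular).

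The groups, the tests, the alternatives, the gene lists, the cell type markers and the rule for naming genes were fixed before the data were examined, with the exceptions stated here. Genes with a mean stabilised value at least 1 above the lowest were tested, which left 10803. For the knockout as such, the clone was the unit: the 2 cultures of each line were averaged, and limma with a mean-variance trend compared the 4 clones with the single parental value, whose spread was taken to equal that among clones. For each clone against the parental line, limma fitted all 10 libraries as 5 groups, and a limma F test compared the 4 clones with each other. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, over 33 of the 34 lists fixed for the bulk data, since the fibroblast list had fewer than 3 measured members. R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used. Because whole reads could be recovered, edgeR's quasi-likelihood test on those reads was added after the data were seen.

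Simulated data with 100 genes changed 2-fold and 100 changed 4-fold among the 10803 were run through the same steps. For the clones against the parental line with the clone as the unit, 26 and 93 of them were recovered, with 11 false calls. Each simulated change had one size in all 4 clones, so these counts do not cover changes whose size differs among clones. In the data the same test called 0 genes and missed Bap1. For clone 1 alone, 93 and 100 were recovered, with 12 false calls. The list percentiles of the single-cell comparison of the skin matrices were tested on simulated data as well: a changed list came out at percentile 100.0, and 2 of 40 unchanged lists fell outside the central 95%.

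The planned rule named the 8 largest rises and 8 largest falls among genes past the threshold with the clone as the unit, and none passed. The 8 largest rises and falls among genes past the threshold with one sign in all 4 clones are named in their place, a pick made after the values were seen. The rule further took up to 4 members per list with the smallest p, the 3 largest rises and falls per clone, and the 6 smallest p among clones, leaving out predicted genes. Chromosome and gene coordinates come from the reference gene table of GRCm38, which matched 13190 of the 13202 gene identifiers.

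Single cells were handled with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6 and igraph 0.11.9. Cells with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs were kept, and each matrix was clustered on its own with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Scrublet marked 111 cells (1.18%) of the matrix labelled KO ocular, which were removed, and 0 cells of the other 3, where it did not work, so doublets remain in those. Clusters were named from the fixed markers and are called "X-like". The first of 2 naming rules tried asked melanocytic markers to exceed 2-fold their level in named other cells. It left clusters with high melanocytic markers unnamed, named none in the matrix labelled WT ocular and gave shares that swung with the settings, so it was replaced after its results were seen. The rule used was chosen from marker levels before ratios between matrices were computed, though Bap1 per cluster had been seen. Under it, a marker counted at 2.0 times its median level over the clusters and in 20% of the cells, and a cluster needed 3 markers. A melanocytic-like cluster needed a melanocytic marker level at least 70% of the way from the lowest to the highest cluster. Clusters with more markers of another class than of their own among their 10 leading genes, melanocytic-like clusters apart, or of low UMI count with no leading marker, stayed unnamed, as did those with the liver gene Alb among the leading genes and those at a melanocytic marker level that had markers of another class but under 3 of them leading. These exceptions were set after the clusters had been seen.

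No tumour was replicated, so no test was run between matrices and no p is given. UMIs were summed over melanocytic-like cells and scaled to their total as CPM over the 19059 genes listed in all 4 matrices. Exact Poisson or binomial 95% intervals cover counting error only. A list is described by its median log2 ratio, with 1.0 CPM added, and by that median's percentile among 10000 random lists matched on mean expression. Except under the alternatives, in the tests of explanations and where all melanocytic-like clusters are stated, expression is compared as a class only over clusters whose 10 leading genes held no more markers of another class than of their own, a restriction applied after values had been seen. It kept 4 of 5 melanocytic-like clusters of the matrix labelled WT skin, 6 of 9 of KO skin and 5 of 5 of KO ocular, and left out 15.8%, 25.3% and 0% of all cells of the matrix, where melanocytic-like cells were 48.0%, 74.9% and 42.0%. It kept 0 of 2 in the matrix labelled WT ocular, whose clusters are therefore given by number. Without the restriction the Bap1 log2 ratio between the skin matrices was 0.19 in place of 0.21. Lists of T-cell and macrophage states are not reported, because T- or NK-like cells numbered 89 to 112 per matrix where they were found, and 1 macrophage-like cluster of the matrix labelled WT skin had the B-cell genes Igkc and Ighm among its leading genes.

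Alternatives covered the filter on low values, median centring and quantile normalisation of the libraries, the trend, the replicate number as a block, the library as the unit, the line as a random block, edgeR, each library and each clone left out, the estimated inter-gene correlation and fry. For the gene lists, each library left out and both ways of scaling the libraries were added after the data were seen, as were, for the single cells, the doublet score, no mitochondrial filter together with doublets kept, the marker level and the clusters included. For the single cells they covered the UMI minimum, doublets, the clustering resolution, the melanocytic marker level, thinning to 1500 UMIs per cell, and the clusters included.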

Results

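The study asked what the loss of BAP1, a nuclear deubiquitinase and tumour suppressor lost in many uveal melanomas, does in melanocytes, and whether the site at which a tumour grows, skin or eye, matters. RNA was measured in 10 libraries of Melan-a cells: the unedited parental line (WT) and 4 BAP1 knockout clones, with 2 cultures of each. The recovered depth was 37.9 and 40.6 M reads in the parental cultures, 46.8 and 31.8 M in clone 1, 41.3 and 43.1 M in clone 2, 35.9 and 32.8 M in clone 3, and 35.6 and 30.8 M in clone 4. The parental cultures stood closest to sampling noise, with a mean chi-square per gene of 2.65 and a median of 1.02, against means of 11.2 to 76.4 in the clones, and were counted as 2 samples. Single cells of tumours were measured in 4 matrices, which the submitters named WT skin, KO skin, WT ocular and KO ocular, with 1 matrix of each and no replicate. After filtering they held 11682, 13111, 26143 and 9287 cells.

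The first question was whether Bap1 itself was lower in the knockout cells. Bap1 (ENSMUSG00000021901, chromosome 14, 31251352 to 31259930 on GRCm38) stood at 4413 and 4356 normalised reads in the parental cultures. It fell in each of the 4 clones, to 747 and 650 reads in clone 1, 1058 and 1115 in clone 2, 1183 and 1089 in clone 3, and 487 and 356 in clone 4. The cultures of the clones kept from 8.1% to 27% of the parental mean. On the log2 scale the clones differed from the parental line by −2.38, −1.85, −1.79 and −2.94, a mean of −2.24 (SD 0.54, n = 4 clones), and the highest of the 4 limma adjusted p-values was 6.69e-06. Every clone label therefore went with a lower Bap1 level, and which exon was edited is not given in the sources used here.

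**Figure D1:**
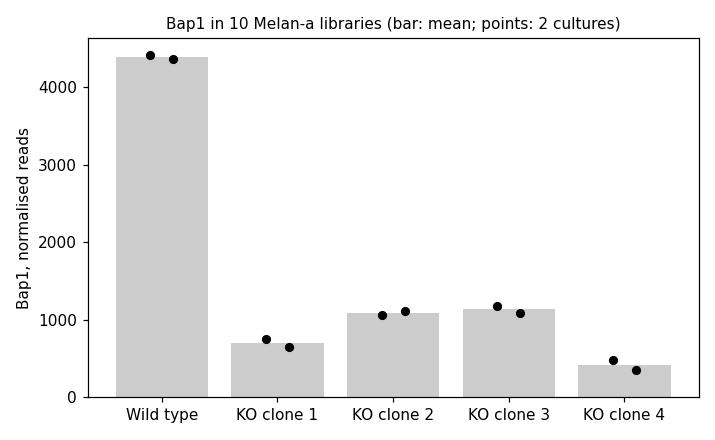
Normalised Bap1 reads in the parental Melan-a line and the 4 knockout clones, with bars for the line mean and points for the 2 cultures of each line. The clones lie between 356 and 1183 reads, below the 4356 and 4413 reads of the parental cultures.

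The next question was which genes changed whichever knockout clone was looked at. No line that was edited and cloned but kept Bap1 was among the libraries. Editing, cloning and time in culture therefore cannot be told apart from the loss of BAP1 in changes common to the clones. Serpine2, a secreted inhibitor of serine proteases, fell in all 4 clones, from 3362 and 3356 normalised reads in the parental cultures to 868 and 936 in clone 1 and to between 22.8 and 55.7 in the cultures of clones 2, 3 and 4. Sparcl1, a matricellular glycoprotein, fell as well (mean log2 difference −3.53, SD 0.81, n = 4 clones), as did Atp1b2, a beta subunit of the sodium-potassium pump (−2.97, SD 0.66). Abcc2, an export pump for organic anions, rose by 2.20 (SD 0.33), from 1270 and 1234 reads to between 5046 and 9263. Tec, a non-receptor tyrosine kinase, rose by 1.90 (SD 0.48), and Pde10a, a phosphodiesterase that degrades cyclic nucleotides, by 1.46 (SD 0.58).

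The other large falls common to the 4 clones were those of Hsd17b11, a lipid-droplet dehydrogenase (−2.73, SD 0.89), Pros1, the anticoagulant protein S (−2.67, SD 1.02), Slc7a2, a transporter of cationic amino acids (−2.63, SD 1.31), the complement gene C4b (−2.61, SD 1.26) and Emb, a partner of monocarboxylate transporters (−2.54, SD 1.32). Reads of C4b may be shared with its near-copy C4a. The other large rises were those of Firre, a long non-coding RNA of the X chromosome (1.30, SD 0.31), Gask1b, a Golgi kinase-like protein (1.22, SD 0.46), Tbc1d2, a Rab GTPase-activating protein (1.20, SD 0.41), Abca12, a lipid transporter (1.18, SD 0.31), and Srrt, which acts with the nuclear cap-binding complex (1.18, SD 0.19). Both Tap1 and Tap2, which carry peptides to MHC class I, fell in all 4 clones, with means of −1.19 and −1.61, as did Kdr, the VEGF receptor 2 (−2.11). The highest adjusted p among the clones, by limma, was 2.38e-05 for Serpine2, 6.08e-06 for Abcc2, 0.000101 for Tap2, 0.00016 for Kdr, 0.00173 for Tap1 and 0.026 for Pde10a. Serpine2 lies on chromosome 1 (79794317 to 79858665) and Abcc2 on chromosome 19 (43782308 to 43838332).

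In all, 227 genes passed the limma threshold with one sign in all 4 clones, 57 higher and 170 lower (106 and 165 after quantile normalisation), and 166 by edgeR. Lists as long as those of the 4 clones but independent of each other would share 0.6 higher and 1.2 lower genes. Part of the excess may come from the shared parental cultures, which are too few to split. In 20 simulations of unchanged clones against the same controls, at most 0 genes were shared. The simulated clones had no changes of their own, so that count gives no baseline for the 227. With the clone as the unit, limma called 0 genes at an adjusted p under 0.05, with 671 at an unadjusted p under 0.05, and edgeR called 0; the adjusted p of Bap1 itself was 0.735. The count of 227 was 32 or 34 without parental replicate 1 or 2, 91 without clone 1 replicate 2, 118 without clone 3 replicate 1 or replicate 2, and 352 without clone 4 replicate 1. Leaving out either of the parental cultures ended the calls in all 4 clones for Srrt (highest adjusted p 0.0631), C4b (0.0852), Pros1 (0.117), Slc7a2 (0.0658), Sparcl1 (0.087), Firre (0.112), Tbc1d2 (0.165), Emb (0.139) and Pde10a (0.235). Those of Firre, Tbc1d2, Emb and Pde10a also ended without clone 1 replicate 2, and that of Pde10a without either culture of clone 3. Those of Bap1, Abcc2, Serpine2, Tec, Atp1b2, Hsd17b11, Gask1b, Abca12, Tap1, Tap2 and Kdr held whichever of the 10 libraries was left out.

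**Figure D2:**
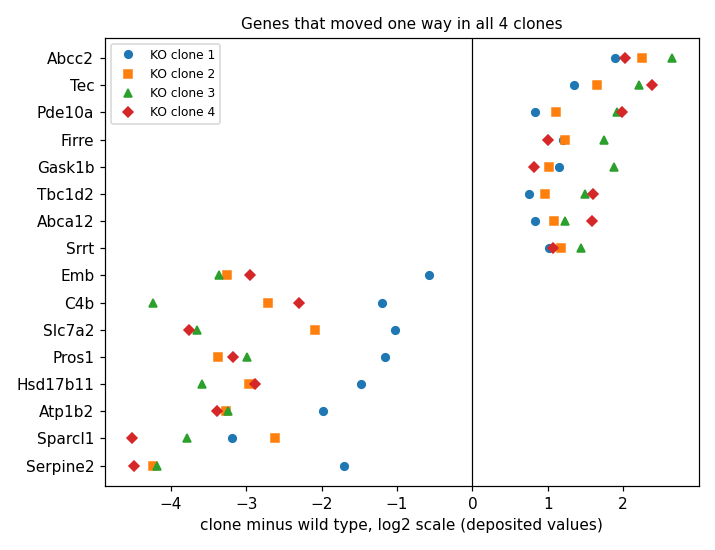
Difference from the parental line in log2 units for the 16 genes with the largest rises and falls common to the clones, with one marker shape per clone (mean of 2 cultures). Serpine2 runs from −1.71 in clone 1 to −4.50 in clone 4, and Abcc2 from 1.89 to 2.64.

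Gene groups fixed in advance were then compared between the clones and the parental line. Interferon and MHC class I genes were lower as lists. Of 15 type I interferon genes, 0, 7, 13 and 10 fell in clones 1 to 4, among them Ifit1, which binds foreign RNA (−0.36, −1.65, −1.64 and −1.93 in clones 1 to 4), and Rsad2, the antiviral enzyme viperin (−0.47, −1.79, −2.44 and −2.10). The list fell by camera (median −0.44, with 0.09 in clone 1, adjusted p = 0.000433, and adjusted p = 0.758 with an estimated correlation). Of 9 interferon-gamma genes, 7, 8 and 6 fell in clones 2, 3 and 4, among them the GTPase gene Irgm1 (−0.27, −1.20, −1.78 and −1.38), while 1 rose in clone 1 and 1 in clone 2. That list had a median of −0.76 (adjusted p = 0.00197, and adjusted p = 0.758 with an estimated correlation). Of 15 genes of MHC class I presentation, 2, 6, 8 and 6 fell in clones 1 to 4 and 3, 1 and 1 rose in clones 2, 3 and 4 (median −0.26, adjusted p = 0.0037, and adjusted p = 0.758 with an estimated correlation). They included the class I heavy chain H2-D1, one of a family of near-copies, at −0.65, −1.81, −1.98 and −1.36.

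Ribosomal protein and cell cycle genes were higher as lists, though the cell cycle genes were not in clone 3. The 30 ribosomal protein genes, many of which have pseudogene copies, had a median of 0.29 (adjusted p = 3.78e-05, and adjusted p = 0.758 with an estimated correlation), with 0, 1, 9 and 4 rising in clones 1 to 4 and 1 falling in clone 3. After quantile normalisation their median was 0.16 (adjusted p = 0.0115). The 24 S-phase genes had a median of 0.30 (0.19, 0.38, −0.01 and 0.45 in clones 1 to 4, adjusted p = 0.00197, and adjusted p = 0.758 with an estimated correlation), with 0, 8, 9 and 10 rising and 1 falling in each of clones 3 and 4. They included Cdt1, which licenses replication origins (0.29, 0.62, 0.91 and 0.79), and the helicase subunit Mcm6 (0.43, 0.70, 0.53 and 0.76). The 24 genes of G2 and M phase had a median of 0.25 (0.26, 0.74, −0.20 and 0.11 in clones 1 to 4, adjusted p = 0.0214, and adjusted p = 0.758 with an estimated correlation), of which 21 rose in clone 2, 2 in clone 4 and 3 fell in clone 3, and a median of 0.40 after quantile normalisation (adjusted p = 0.000256). Without clone 1 replicate 1 or clone 4 replicate 2 the last call ended (highest adjusted p 0.0828), and its highest adjusted p with any one clone left out was 0.235. With the clone as the unit, 0 members of any list passed over all genes by limma, and adjusted over the list alone 2 passed in MHC class I presentation and 1 each in interferon-gamma, the BAP1 complexes (Bap1), the class 2 uveal melanoma genes that are lower, and the immune and endothelial markers.

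The other 27 lists did not pass, with camera adjusted p-values from 0.108 to 0.704. Pigmentation genes had a median of −0.10 (adjusted p = 0.407), with Mc1r, the melanocortin receptor, at 0.64, 0.83, 1.42 and 1.62 in clones 1 to 4, of which clone 1 did not pass (limma adjusted p = 0.059). Subunits and partners of BAP1 had a median of 0.18 and a mean of −0.03, and camera's direction was up (0.407). Class 2 uveal melanoma genes that are higher had a median of −0.38 and a mean of 0.23, with a direction of down (0.704), and those that are lower a median of −0.26 (0.13). Schwann cell markers had a median of −0.66 (0.13), neural adhesion genes −0.17 and MAPK feedback genes 0.21 (0.108 each), and matrix and EMT genes −0.24 (0.173). With the replicate number as a block and each library as the unit, Schwann cell markers (0.0276), matrix and EMT genes (0.0274) and neural adhesion genes (0.0323) passed. With the clone as the unit and an estimated correlation, the camera adjusted p of each of these lists was 0.758. The adjusted p was 0.584 for Polycomb genes, 0.312 for Hox genes, 0.589 for neural crest genes and for Wnt targets, 0.44 for p53 targets, 0.577 for MHC class II, 0.529 for checkpoint ligands, and 0.704 for YAP targets, DNA repair and the mitochondrial and nuclear RNAs that mark RNA quality. It was 0.407 for chemokines, for immediate early genes, for glycolysis and hypoxia and for keratinocyte markers, 0.319 for ferroptosis, 0.281 for cholesterol synthesis, and 0.216 for the unfolded protein response and for immune and endothelial markers. It was 0.302 for oxidative phosphorylation (0.766 with an estimated correlation), which passed after quantile normalisation (median −0.13, adjusted p = 0.00578).

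Each clone was then set against the parental line, and the clones against each other. Mrgprb1, a receptor known from mast cells, rose from 6.6 and 6.1 normalised reads in the parental cultures to 1498 and 1257 in clone 1, 8968 and 8349 in clone 2 and 1204 and 992.6 in clone 3, and stood at 18.2 and 10.0 in clone 4. Its relative Mrgprx2 differed by 1.66, 4.04, 1.59 and −0.21, and reads of this gene family may be shared. Sez6l, a neuronal membrane protein, reached 4341 and 4196 reads in clone 2 and at most 4.6 in every other culture. Syt4, a synaptotagmin of vesicle release, rose by 1.58, 2.01 and 2.06 in clones 1, 2 and 4 and fell by 4.97 in clone 3, from 6574 and 6648 reads to 79.9 and 55.0. Fibronectin (Fn1) differed by −1.86, −2.05 and −5.30 in clones 2, 3 and 4. The limma F test among the clones gave adjusted p-values of 5.37e-09 for Mrgprb1, 1.46e-07 for Mrgprx2, and 2.57e-09 for both Sez6l and Syt4.

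Among the largest changes of clone 3 were rises in Steap1, a metalloreductase (2.86), and Nrxn2, a synaptic adhesion molecule (2.78), and a fall in the receptor Gpr37 (−4.72). Among those of clone 4 were rises in the immunoglobulin heavy chain Ighm (4.18), the prolactin relative Prl7a2 (3.79) and the potassium channel Kcnj13 (3.68). Htatip2, an oxidoreductase, fell in clones 1 and 4 (−2.48 and −2.57) and stood at 0.27 and 0.31 in clones 2 and 3. The receptor Cd200r4 rose in clone 1 (1.41) and fell in clone 4 (−2.96), with an adjusted p of 1.53e-07 in the F test.

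By limma, 378 genes changed in clone 1 (124 higher and 254 lower, or 204 and 269 after quantile normalisation), 2822 in clone 2, 4304 in clone 3 and 3941 in clone 4, and edgeR called 299, 2778, 4238 and 3863. The F test found 4806 genes that differed among the clones by limma and 4670 by edgeR. The count for clone 1 was 57 or 61 without parental replicate 1 or 2, 157 without clone 1 replicate 2, 194 without clone 3 replicate 1 or replicate 2, 639 without clone 4 replicate 1 and 635 without clone 4 replicate 2. The counts without parental replicate 1 and without parental replicate 2 were 1088 and 1161 in clone 2, 2320 and 2282 in clone 3, and 2026 and 1925 in clone 4. Clone 2 gave 1571 without its replicate 2, and clone 3 gave 2518 and 2420 without its replicates 1 and 2, which brought the F test to 2966 and 2954. A line left with 1 culture was assumed to vary like the others.

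Whole chromosomes differed from the parental line in some clones, and chromosome 5 in both clones 3 and 4. In clone 3 the median gene of chromosome 5 stood 0.40 above the clone's median gene on the log2 scale of reads (708 genes, 0.39 and 0.41 in its cultures) and that of chromosome 15 at −0.32 (445 genes). In clone 4 the medians were 0.27 for chromosome 5, −0.28 for chromosome 7 (808 genes) and 0.31 for chromosome 12 (383 genes), and in clone 2 they were 0.28 for chromosome 10 (526 genes) and −0.22 for chromosome 12. These were the 7 of 80 chromosome and clone pairs with a median at least 0.2 from 0, a limit chosen after the medians were seen. With limits of 0.15 and 0.25 the pairs numbered 12 and 6, and clone 1 had 0 pairs at 0.2 and chromosome 18 (−0.16) at 0.15. Of the genes with the largest rises and falls common to the clones, Tec, Srrt, Sparcl1 and Hsd17b11 lie on chromosome 5. Their differences in clones 3 and 4 may include the shift of that chromosome, though Sparcl1 and Hsd17b11 fell against it. The positions of the other genes named for single clones or lists were not read.

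**Figure D3:**
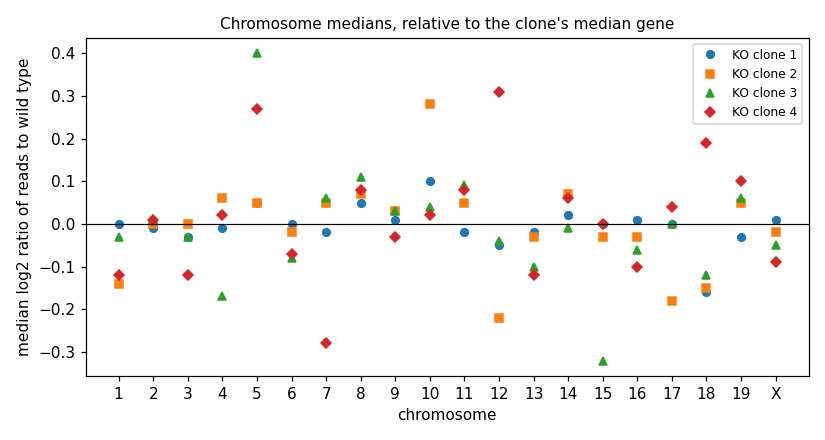
Median log2 ratio of reads to the parental line for the genes of each chromosome in each clone, relative to the clone's median gene. Chromosome 5 stands at 0.40 in clone 3 and 0.27 in clone 4, and chromosome 15 at −0.32 in clone 3.

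The tumour matrices were read for the cells they held. In the matrix labelled WT skin, 48.0% of cells were melanocytic-like (exact binomial 95% interval 47.1 to 49.0), 20.8% macrophage-like, 7.88% neutrophil-like (4.71% to 14.8% under other settings) and 3.89% fibroblast-like, with 17.2% unnamed. The macrophage-like cells included the 270 of cluster 7, which had the B-cell genes Igkc and Ighm among its leading genes. At resolution 0.5, 0.633% of cells were named B-like. The unnamed cells included the 902 of cluster 0, which had the liver genes Alb, Apoa1, Apoa2 and Fabp1 among its leading genes and a melanocytic marker level of 84.5%. In that labelled KO skin, 74.9% were melanocytic-like (74.1 to 75.6), 10.8% macrophage-like (10.2% to 16.1% under other settings), 2.72% neutrophil-like, 1.93% endothelial-like and 1.42% fibroblast-like. The matrix labelled KO ocular held 42.0% melanocytic-like cells (41.0 to 43.0), 12.5% neutrophil-like (18.5% to 20.4% under 5 other settings) and 8.78% macrophage-like, with 19.3% unnamed. In that labelled WT ocular, 27.0% were melanocytic-like (26.4 to 27.5), all in clusters 0 and 2. Each of these clusters had 1 marker of another class and 0 melanocytic markers among its 10 leading genes. A further 13.5% of that matrix were macrophage-like, and cells of the eye were present. There 9.87% of cells were rod-like (15.1% without the top 5% by doublet score, and not named at resolution 0.5 or 1000 UMIs), 3.32% corneal epithelium-like (0.80% to 1.14% under 4 other settings), 1.64% Müller glia-like (1.56% to 2.23%) and 1.17% cone-like (up to 1.72%, and not named at resolution 0.5). Some clusters of other classes had a melanocytic marker level above 70%: the rod-like cluster of the matrix labelled WT ocular (75.7%), the neutrophil-like clusters of WT ocular (80.4%) and KO skin (73.3%), and macrophage-like cluster 10 of WT skin (82.9%), so doublets or free RNA are not separated from these shares. No share is given for erythroid-like cells, whose clusters reached 94.5% and in 1 case also had neutrophil genes among the leading genes. T- or NK-like cells made up 0.762% of the matrix labelled WT skin (not named at 1000 UMIs), 0.854% of KO skin (0.498% at 1000 UMIs, and not named at resolution 0.5) and 1.12% of KO ocular. The matrices differ in depth and that labelled WT ocular in assay, so the shares describe each matrix, and no direction is drawn between them.

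The skin matrices address what BAP1 loss does in a tumour, with 1 tumour per label. Bap1 was not lower in the matrix labelled KO skin: melanocytic-like cells held 50.3 CPM of Bap1 there (exact Poisson 95% interval 48.2 to 52.4) against 43.4 CPM (41.3 to 45.6) in that labelled WT skin, a log2 ratio of 0.21 (0.12 to 0.31). The ratio was 0.01 (−0.08 to 0.11) without the clusters with Igfn1, Adgb or Sfi1 among their leading genes and 0.50 with every cell thinned to 1500 UMIs. Macrophage-like cells held 41.8 and 37.1 CPM. The labels of these matrices come from their names alone. The cultures of the clones kept 8.1% to 27% of the parental Bap1 reads, a fall not seen between these matrices. A probe or tag outside the edited part could count a transcript that the edit had not lowered, and its position is not given. The Bap1 count therefore does not bear out the label KO skin and does not decide it. Every direction below is one between the matrix labelled KO skin and the matrix labelled WT skin.

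Melanocytic-like cells of the matrix labelled KO skin had higher counts of Mrgprb1 (478 against 0.69 CPM, log2 ratio 9.44, 8.87 to 10.06) and Mrgprx2 (244 against 0.75 CPM, 8.35), of Mcoln3, a lysosomal cation channel (117 against 0.64 CPM, 7.52), of the unconventional myosin Myo16 (59.3 against 0.19 CPM, 8.26), of the potassium channel Kcnt1 (56.3 against 0.33 CPM, 7.41) and of the ephrin receptor Ephb1 (44.7 against 0.30 CPM, 7.20). They had lower counts of C4b (16.1 against 1764 CPM, −6.77, −6.88 to −6.67), Serpine2 (5.46 against 433 CPM, −6.31, −6.50 to −6.13), Pros1 (0.91 against 48.3 CPM, −5.74), the calcium-binding copine Cpne4 (0.29 against 53.9 CPM, −7.55), the membrane metalloproteinase Mmp16 (0.24 against 32.3 CPM, −7.05) and the microtubule protein Map7d2 (0.29 against 19.0 CPM, −6.05). The cells were those of clusters 1, 3, 8 and 13 in the matrix labelled WT skin and 0, 1, 3, 4, 7 and 8 in that labelled KO skin, and free RNA in the droplets may add to every class.

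Of the gene groups, interferon-gamma genes had a median log2 ratio of −0.93 (percentile 0 among 10000 random lists matched on expression), MHC class I presentation −0.62 (percentile 0.14), chemokines −0.65 (0.18), matrix and EMT genes −0.47 (0.05) and S-phase genes −0.39 (0.05), against a median of 0.30 in the cultured clones, where the call ended with an estimated correlation (adjusted p = 0.758). Class 2 uveal melanoma genes that are lower stood at −0.72 (0.87), genes of G2 and M phase at −0.13 (1.29) and neural adhesion genes at −0.42 (2.26), and at the other end immediate early genes at 0.57 (98.2) and Polycomb genes at 0.51 (98.1). Fibroblast markers stood at −0.48 (4.79) and Schwann cell markers at −0.70 (0.58). Macrophages express many of the interferon, MHC and chemokine genes and fibroblasts many of the matrix genes, and the free RNA of both may be counted in other cells of the same matrix, which was not measured. Type I interferon genes stood at −0.33 (3.49), pigmentation genes at −0.13 (18) and subunits and partners of BAP1 at 0.50 (89.4). Mitochondrial and nuclear RNAs that mark RNA quality moved with the same comparison, with a median of −2.77 (percentile 0). These percentiles describe the 2 matrices, with no test.

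Genes that had changed in all 4 cultured clones were next followed in the skin matrices. Of the genes that fell in the clones, 106 of 152 counted in melanocytic-like cells had lower counts in the matrix labelled KO skin, with a median log2 ratio of −0.69 (percentile 0). Of those that rose, 9 of 52 had lower counts, with a median of 0.65 (percentile 100). Over all melanocytic-like clusters, Serpine2, C4b, Pros1 and Atp1b2 (151 against 4.44 CPM) were lower in the matrix labelled KO skin, and Srrt (229 against 125 CPM) and Tec (156 against 102 CPM) were higher. Others went against the cultures: Slc7a2 stood at 69.1 CPM in the matrix labelled WT skin and 75.9 CPM in that labelled KO skin, and Abcc2, at 66.9 and 50.1 CPM, and Abca12, at 174 and 69.95 CPM, were lower in the latter. Pde10a stood at 24.46 and 18.6 CPM over all clusters and at 21.52 and 23.79 CPM over the clusters compared as a class.

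**Figure D4:**
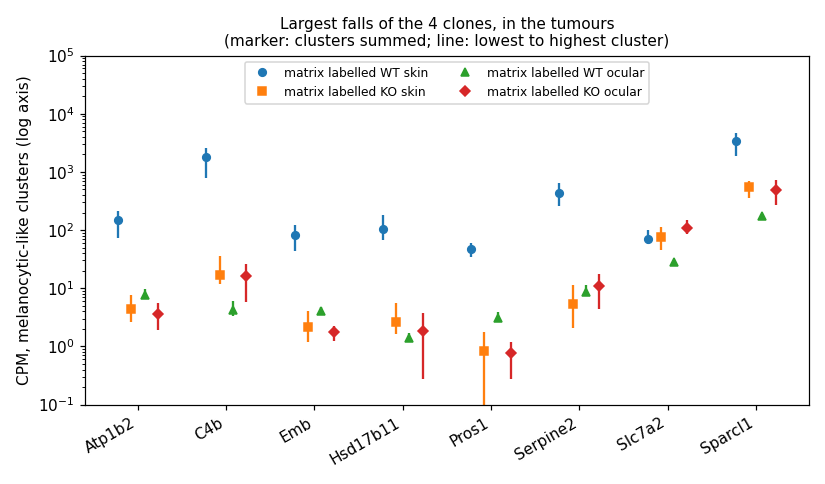
CPM (log axis) of the 8 genes with the largest falls common to the cultured clones, in melanocytic-like cells of the 4 tumour matrices, each line running from the lowest to the highest cluster and each marker giving all clusters summed. Serpine2 ran from 260 to 652 CPM across the clusters of the matrix labelled WT skin and from 2.10 to 11.6 CPM in that labelled KO skin.

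The matrices labelled KO ocular and KO skin address the site of growth, again with 1 tumour each. Melanocytic-like cells of the matrix labelled KO ocular (clusters 1, 2, 3, 6 and 8) had higher counts of Klra17, a lectin-like receptor (29.4 against 0.68 CPM, log2 ratio 5.42, 4.91 to 5.98), of the chemokine Cxcl2 (21.1 against 2.28 CPM, 3.21), of the mitochondrial ADP and ATP carrier Slc25a5 (241 against 26.2 CPM, 3.21) and of Ran, a GTPase of nuclear transport (49.4 against 7.36 CPM, 2.75). Cxcl2 is also a leading gene of neutrophil-like clusters, whose free RNA may be counted in other cells of the same matrix, which was not measured. They had lower counts of the clock gene Per2 (7.33 against 52.3 CPM, −2.83), the signalling regulator Rgs11 (12.02 against 90.6 CPM, −2.91), the metalloproteinase Mmp23 (−3.37), the actin-capping Tmod4 (−2.93), the transcription factor Glis1 (−2.74) and Kank4 (−2.55). Bap1 stood at 33.6 CPM (32.3 to 34.9), a log2 ratio of −0.58 (−0.67 to −0.50). Across these clusters it ran from 23.45 CPM in cluster 3 to 56.7 CPM in cluster 6. Across all 9 melanocytic-like clusters of the matrix labelled KO skin it ran from 39.46 to 67.02 CPM. The interval does not cover this spread among clusters. As lists, S-phase genes (median 0.89, percentile 100), cholesterol synthesis (1.15, 100), oxidative phosphorylation (0.38, 99.9) and DNA repair (0.36, 99.95) were higher, and genes of glycolysis and hypoxia (−0.89, 0), MHC class II (−1.23, 0.51) and Hox genes (−1.26, 0.34) were lower. Also outside the central 95% were genes of G2 and M phase (0.38, 99.99), immediate early genes (0.25, 99.08), neural adhesion genes (0.23, 98.57), ferroptosis genes (0.30, 97.7), type I interferon genes (0.04, 97.7) and subunits and partners of BAP1 (−0.57, 2.21).

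The mitochondrial transcripts mt-Nd1 (2272 against 262 CPM, 3.12) and mt-Nd3 (448 against 53.5 CPM, 3.07) were higher too, and the RNA quality list moved with this comparison (median 2.17, percentile 100). The melanocytic-like cells of the matrix labelled KO ocular had a median of 11207 UMIs, against 4408 in that labelled KO skin. Which clone gave each tumour is not given in the sources used here, so site, clone, tumour and RNA quality cannot be separated.

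The matrix labelled WT ocular has no matrix of the same assay beside it, and its melanocytic-like clusters 0 and 2 each held 1 marker of another class and 0 melanocytic markers among their 10 leading genes, so they are given by number. Across both clusters Serpine2 stood at 7.23 to 11.3 CPM, C4b at 3.33 to 6.13 CPM, Pros1 at 2.60 to 3.97 CPM, Atp1b2 at 6.44 to 9.85 CPM, Sparcl1 at 158 to 182 CPM and Slc7a2 at 26.3 to 31.0 CPM. Bap1 stood at 9.01 CPM in cluster 0 and 6.90 CPM in cluster 2, and macrophage-like cells of the same matrix held 9.53 CPM. A pair of genes chosen after their values were seen went apart: Mrgprb1 stood at 338 to 358 CPM, near its level in the KO-labelled matrices, and Cpne4 at 27.4 to 30.5 CPM, near its level in that labelled WT skin. Other genes ranked above between the skin matrices lay nearer to KO ocular than to WT skin. They were Mrgprx2 (59.0 to 61.9 CPM), Mcoln3 (20.4 to 21.8 CPM), Myo16 (27.7 to 32.9 CPM) and Ephb1 (32.7 to 39.9 CPM). Mmp16 (2.37 to 3.60 CPM) and Map7d2 (1.13 to 1.44 CPM) did so too, while Kcnt1 (1.47 to 2.52 CPM) lay between. The corneal keratin Krt12 (154 to 247 CPM) and the rod genes Gngt1 (150 to 206 CPM) and Pdc (41.8 to 69.1 CPM) were counted in both clusters, and whether free RNA or doublets brought them was not measured.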

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

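The test for a swap of the skin matrices was chosen before its result was seen, and the other tests of explanations here (RNA from other cells, the comparison of cultures, the tests of chromosome copies, the splits that set a lone line apart, the tests of the WT ocular label and that of its assay) were chosen after.

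The 4 clones differed from each other in 4806 genes by the limma F test, and 198 genes rose in 1 clone and fell in another. Among the genes named for changing the same way in all clones, the size of the change differed among clones for Serpine2 (adjusted p = 1.95e-07, −1.71 in clone 1 against −4.50 in clone 4), Emb (1.53e-07), Slc7a2 (1.83e-06), C4b (1.5e-05), Hsd17b11 (8.26e-05) and Pros1 (9.61e-05). The same limma test gave adjusted p = 0.00084 for Pde10a, 0.00112 for Abcc2, 0.0014 for Gask1b, 0.00149 for Abca12, 0.00172 for Tbc1d2, 0.00282 for Atp1b2, 0.00284 for Tec and 0.0497 for Firre. Srrt (0.103) and Sparcl1 (0.0581) did not pass it. When each of the 5 lines in turn was set against the other 4, the 5 splits were too few for a share under 0.05, with 0 genes for the parental line against the clones and at most 1 for any other line.

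Bap1 was counted in melanocytic-like cells of the matrix labelled KO skin at no lower a level than in that labelled WT skin. A swap of the 2 labels is argued against by the genes found in the cultured clones: those that rose in all 4 stood at percentile 99.98 of random lists in KO skin against WT skin, and those that fell at percentile 0. RNA from other cells as the source of the Bap1 count is argued against by its level, 1.14 times that of macrophage-like cells with a lowest ratio of 0.99 between the interval ends, since free RNA is a part of what a droplet holds and would have to make up nearly all of it to give that level. A probe or tag that still counts an edited transcript would leave the level in place only if the transcript itself were not lowered. The cultures of the clones kept 8.1% to 27% of the parental Bap1 reads, which argues against this for the cultured clones. It is not excluded, since the clone that gave the tumour is not given and the fall was not read along the gene. An unusual tumour under the label WT skin, where 902 cells had liver genes among the leading genes, stays open. So does the difference between any 2 tumours, since each label has 1. No biological explanation was tested.

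In the matrix labelled WT ocular, 7 of the 8 genes with the largest falls in the clones stood nearer to KO ocular than to WT skin, while of the 7 counted genes with the largest rises 2 stood nearer to KO ocular and 5 to WT skin. These counts and the percentiles below were taken over all melanocytic-like clusters. They include clusters 0 and 2 of WT ocular, which the comparison as a class left out. Over all genes that changed in all 4 clones, those that fell stood at percentile 2.79 and those that rose at 97.74 of random lists in KO ocular against WT ocular (7.36 and 51.65 without the clusters with Igfn1, Adgb or Sfi1 among their leading genes), but the median log2 ratio of the former was 0.31, with 49 of 148 genes lower in KO ocular, and in WT ocular against WT skin it was −1.42 (percentile 0, 134 of 155 lower). A wrong label is neither shown nor excluded, since these values go both ways and 1 matrix was made with this assay, so that assay and label cannot be told apart. Cpne4, at 27.4 to 30.5 CPM against 0 to 0.25 CPM in the clusters of KO ocular, went against a wrong label, and Mrgprb1 went with one, both chosen after their values were seen. Of the other genes ranked between the skin matrices, Mrgprx2, Mcoln3, Myo16, Ephb1, Mmp16, Map7d2, C4b, Serpine2 and Pros1 stood nearer to KO ocular than to WT skin. Kcnt1 (1.81 CPM) stood between WT skin (0.29 CPM) and KO ocular (10.8 CPM). These ranked genes were picked for the largest ratios between the skin matrices. An unusual matrix labelled WT skin would therefore also leave WT ocular nearer to KO ocular. Their number does not bear on the label, which the single matrix of this assay cannot decide. The site, which the design names, stays open as well and was not tested.

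Whole chromosomes shifted in some clones, in 7 of 80 pairs of clone and chromosome, with chromosome 5 higher in both clones 3 and 4. A difference between the 2 cultures of a clone is argued against, since all 7 shifts had one sign and lay within 2 times of each other in both cultures. Gain or loss of chromosome copies in some or all cells of a clone stays open. Neither the chromosomes read in 3 equal parts, of which 7 of 7 had every part at 0.5 times the whole shift or more, nor the share of genes on the shifted side, at least 70.7%, decides it, because the chromosomes were picked by the medians of the same genes. No biological explanation beyond copy number was tested, and the exome libraries of these lines were not analysed here.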

How the results depend on the processing

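Alternatives added after the data were seen were edgeR, the removal of the 5% of cells with the highest doublet score, no mitochondrial filter with doublets kept, the marker levels of 60% and 80%, the clusters included, and for gene lists each library left out and both scalings. The count of 0 genes with the clone as the unit was also 0 under both scalings, either filter, without any 1 library and by edgeR, and 15 without clone 1. It was 8 with the line as a random block, and 3376 by limma and 3367 by edgeR with each library taken as independent, which counts cultures of a clone as replicates of the knockout. Under the stricter filter, which tests fewer genes, the counts were 105, 1529, 2821 and 2556 for clones 1 to 4, 66 for all 4 clones and 3062 for the F test. With only the 4 libraries of the clone and the parental line, clone 1 had 190 and clone 3 had 7507. A log2 difference of at least 1 left 37 of the 227.

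Leaving out 1 library gave 57 to 639 genes in clone 1, 1088 to 3488 in clone 2, 2282 to 4986 in clone 3, 1925 to 4316 in clone 4, 32 to 352 in all 4 clones and 2954 to 5394 in the F test. The 6 gene lists were 0 with an estimated correlation and 0 by fry. Deviations of same-numbered cultures correlated from −0.128 to −0.074 between the parental line and the clones. They correlated at −0.026 between clones 3 and 4 and from 0.11 to 0.727 in the other 5 pairs of clones. The replicate numbers were not taken to pair the cultures, because the parental line did not share these deviations. A deviation shared by same-numbered cultures of some clones is not excluded. With the replicate number as a block and each library as the unit, 3979 genes passed for the knockout, against 3376 with libraries as the unit and no block. The block gave 616 for clone 1 and 356 in all 4 clones, and 9 lists, adding those of matrix and EMT (adjusted p = 0.0274), neural adhesion (0.0323) and Schwann cell (0.0276) genes.

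The melanocytic-like share of KO ocular was 43.9% at resolution 0.5, 44.1% with doublets kept, 52.5% at 1000 UMIs, 43.1% without the top 5% by doublet score and 48.3% without the mitochondrial filter and with doublets kept. That of KO skin was 67.3% at level 80%, 49.6% in the clusters compared, 76.8% at 1000 UMIs and 77.2% without the top 5%. That of WT ocular was 33.0% at level 60%, 32.1% at resolution 0.5, 34.9% at 1000 UMIs, 29.1% without the top 5% and 19.8% without the mitochondrial filter and with doublets kept. That of WT skin was 32.3% in the clusters compared, 51.0% at resolution 0.5 and 54.5% at 1000 UMIs. The neutrophil-like share at resolution 0.5, at 1000 UMIs, without the top 5%, and without the mitochondrial filter and with doublets kept, was 20.4%, 18.5%, 19.8% and 19.97% in KO ocular (20.3% with doublets kept alone), 6.01%, 7.38%, 7.32% and 8.99% in WT ocular, and 14.8%, 4.71%, 12.4% and 6.69% in WT skin. In KO skin it was 1.77% at 1000 UMIs and 2.43% without the top 5%. The cause was not tested.

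The Bap1 log2 ratio of KO ocular to KO skin was −0.62 thinned and −0.65 without the clusters with Igfn1, Adgb or Sfi1 among their leading genes, that of KO skin to WT skin 0.50 and 0.01, and that of WT ocular to WT skin −2.06 thinned. A pair of list medians reversed: immediate early genes in KO ocular against WT ocular at −0.02 with 1000 UMIs and −0.14 without those clusters, and G2 and M phase genes in WT ocular against WT skin at 0.04 thinned. The cause was not tested. Of the other values, those of single genes, lists and smaller cell classes, 3626 were counted as unchanged under the alternatives fixed in advance. A further 277 passed the threshold under the alternative alone, 11 no longer passed and 30 moved. A single-cell list that passed in neither setting counted as unchanged whatever its direction. For single-cell lists that passed under the alternative alone, the direction was not compared. Under those added later these counts were 1147, 142, 22 and 47. Single-cell ratios within their counting intervals are not resolved at this depth.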

Other observations

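The values in this part were chosen after the data were seen, apart from the membership of the gene lists, and no further explanation was tested.

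Some genes of surface and secreted proteins were read singly. Thrombospondin 1 (Thbs1) differed by −0.79, −2.99, −2.33 and −3.75 in clones 1 to 4, osteopontin (Spp1) by −0.59, −2.41, −2.62 and −1.88, and Cd47, a ligand that restrains phagocytosis, by −0.43, −1.15, −1.24 and −1.28. Lgals9 differed by −0.60, −1.53, −1.99 and −1.09, while Lgals3, another galectin, rose in clones 2, 3 and 4 (0.61, 1.61, 1.26 and 1.16). Clone 1 did not pass the limma threshold for these 5 genes. Csf1, the growth factor of macrophages, fell in all 4 clones (−0.96, −1.21, −1.39 and −2.47, highest limma adjusted p 0.033). Its call in all 4 ended without either parental culture, either culture of clone 1 or either culture of clone 3 (highest adjusted p 0.25).

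Of the 8 measured Schwann cell markers, 4, 6 and 4 fell in clones 2, 3 and 4, 0 fell in clone 1 and 1 rose in clone 3, and the list did not pass (camera adjusted p = 0.13, 0.758 with an estimated correlation, and 0.0276 with the replicate number as a block and each library as the unit). Myelin basic protein (Mbp) differed by −0.41, −1.79, −2.10 and −2.09 in clones 1 to 4 and the cadherin Cdh19 by 0.20, −1.50, −2.84 and −1.89.

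Hsd17b11 and Sparcl1, both among the largest falls common to the clones, lie close together on chromosome 5 (103989765 to 104021796 and 104079108 to 104114088 on GRCm38). The first principal component of the 10 libraries held 49.6% of the variance and the second 18.7%.

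Smaller classes of cells were also named, most of them not under every setting. The matrix labelled KO ocular held 0.603% B-like cells (0.571% to 0.607% under other settings), 0.70% like pigment or ciliary epithelium (not named at resolution 0.5) and 0.226% mast-like cells (not named at 1000 UMIs). That labelled KO skin held 0.793% B-like cells (0.425% without the top 5% by doublet score, and not named at resolution 0.5 or 1000 UMIs). Keratinocyte-like cells made up 0.36% of WT skin (not named at resolution 0.5) and 0.972% of WT ocular (2.87% at resolution 0.5), and were named in neither matrix without the mitochondrial filter and with doublets kept.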
